A study of Saccharomyces cerevisiae with 17 samples.

How the data were processed

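Total RNA of yeast in mid-log phase was extracted with hot phenol and treated with DNase, and poly(A) RNA was made into libraries with a directional kit, per the labels' protocols. The 17 libraries come from 4 genotypes and 2 sequencing batches. The deposited values are raw read counts per gene, 1 column per library. Reads were aligned to sacCer3 with STAR 2.7.11a and counted per gene with featureCounts of Subread 2.0.5, per the submitters' processing notes. The annotation, the strand setting and the handling of reads with several positions are not given in the sources used here. The table held 6692 genes, of which 6008 are in the RefSeq annotation and 684 are not, and 112 had 0 reads in each library. All value columns were used.

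Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with genotype as the group (6162 genes), scaled by TMM and fitted with the quasi-likelihood model (robust) with terms for genotype and sequencing batch. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The model had 5 coefficients and 12 residual degrees of freedom, and the common dispersion was 0.005254. The SE of a log2 fold change was its size over the square root of the F statistic. CPM values carry no batch correction, and their mean and SD run over 3 sets of matched libraries per genotype. Correlations used log CPM with a prior count of 2. Libraries held 19.75 to 59.48 M counted reads.

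Comparisons were each deletion with wild type, the deletions with one another, and the effect of nmd4Δ between batches. The gene lists, chosen before the values were seen, numbered 26. They were NMD substrates, frameshift mRNAs, mRNAs with upstream reading frames, intron-containing meiotic genes, interrupted reading frames, decay factors, Gcn4-dependent, pyrimidine, ribosomal protein, ribosome assembly, stress, allantoin and nitrogen, thiamine, phosphate, iron, sulfur, respiratory, glycolysis, glucose-repressed, ergosterol, seripauperin and TIR, MATa, MATalpha, early meiotic and mitochondrially encoded genes, and strain markers. The last was used only to check labels. Lists of at least 3 measured genes were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and again with an estimated one, and adjusted over the lists of each comparison. In the main fit camera took matched libraries as separate, so its p-values do not allow for the matching. A count adjusted over the list alone repeats the adjustment within the list. The 4 annotation classes formed a separate family. Of the list members, 6 were not found in the table.

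Genes are named by a rule written before the values were seen. It took the 10 largest rises and falls against wild type and the 5 largest between deletions, among called genes with a standard name, a mean of at least 10 CPM and every library on the same side, then the 4 called members of each list with the lowest p, the deleted genes and their 2 neighbours on each side. Other genes in the text were chosen after their values were seen.

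Libraries were compared after their counts were seen, by chi-square over genes with an expected count of at least 5 and by residual correlation over genes with a mean count of at least 1000. The matched libraries entered a limma voom fit as a block (consensus correlation 0.7185), were summed, or were reduced to 1 per set. The summed and the 1-per-set fits had no batch term. Other alternatives, fixed beforehand, were DESeq2 1.42.0, its scaling in edgeR, no filter, no batch term, each batch alone, only the 2 groups compared, no robust fit, replicate numbers as a block and leaving out each library.

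The pipeline was tested on simulated data of 6029 genes with known changes. Of genes changed 2-fold it called 91.0% for upf1Δ, 93.9% for nmd4Δ and 96.9% for ebs1Δ, and of genes changed 1.5-fold 83.3%, 86.4% and 90.9%. False calls were 3.23%, 5.18% and 1.06% of all calls. When unchanged groups were simulated with the shared effects of matched libraries, the nmd4Δ comparison made 26.1 false calls on average and 42 at most, and the other 2 at most 3. No gene changed in that simulation, whereas 28.0% of tested genes were called in the real nmd4Δ comparison. Its dispersions came from the fit that takes matched libraries as separate. It therefore does not give the number of false calls among the real ones.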

Results

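Poly(A) RNA of haploid budding yeast was sequenced from wild type cells and from strains lacking 1 of 3 genes of nonsense-mediated mRNA decay (NMD), the pathway that degrades mRNAs whose translation stops too early. UPF1, listed in the count table under its systematic gene name NAM7, encodes the RNA helicase at the centre of the pathway, and NMD4 and EBS1 encode proteins that bind Upf1. The strains derived from BY4741, a MATa laboratory strain, carried a LEU2 plasmid and grew to mid-log phase in synthetic medium without leucine. The 3 deletion strains share a KlURA3 marker, and no library with the marker and without a deletion was analysed here. In comparisons with wild type its effect therefore cannot be told apart from that of the deleted gene. The wild type had 5 libraries, upf1Δ 3, nmd4Δ 6 and ebs1Δ 3. Batch 1 held 11 libraries of 19.75 to 29.67 M counted reads, and batch 2 held 6 of 40.37 to 59.48 M, of wild type and nmd4Δ only. Expression is given as CPM (reads relative to the TMM-scaled library size, mean ± SD) and changes as log2 fold changes ± SE from edgeR's quasi-likelihood test on 6162 genes, with coordinates on sacCer3. P-values measure only the spread between these libraries.

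In 5 cases a batch 2 library matched 1 batch 1 library of its genotype far better than the others. Replicates 4, 5 and 6 of nmd4Δ matched 1, 2 and 3, and wild type replicates 3 and 4 matched 1 and 2. With a shift between batches removed for each gene, the chi-square per degree of freedom within matched nmd4Δ libraries was 2.90, against 18.3 to 33.9 under the 5 other ways of matching. In wild type it was 2.68 against 8.22 to 59.8. With no shift removed, the matched nmd4Δ pairs had 9.95 to 14.3, against 24.9 to 45.9 for unmatched pairs across batches and 12.3 to 40.5 for pairs within a batch. Matched libraries were therefore averaged before each mean and SD, which leaves n = 3 sets per genotype. A second fit, limma voom with the matched sets as a block, was added after the libraries had been compared, and its calls are given for each comparison.

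The deleted genes were nearly free of reads in the strains labelled as lacking them. NAM7 (YMR080C, chromosome XIII, 426712 to 429627) had 5 to 59 reads per upf1Δ library and 4535 to 10325 per wild type library, or 0.967 ± 1.19 against 183 ± 3.02 CPM (SD, n = 3 in each). NMD4 (YLR363C, chromosome XII, 852495 to 853151) had 17 to 61 reads in nmd4Δ and 805 to 1765 in wild type, or 0.957 ± 0.212 against 31.2 ± 0.805 CPM. EBS1 (YDR206W, chromosome IV, 862054 to 864708) had at most 1 read in ebs1Δ and 3325 to 6950 in wild type. NMD4 mRNA rose in upf1Δ by 1.68 ± 0.071 on the log2 scale and in ebs1Δ by 0.68 ± 0.072, and EBS1 mRNA rose in upf1Δ by 0.73 ± 0.067. EBS1 did not pass in nmd4Δ (-0.05 ± 0.050), nor did NAM7 in nmd4Δ (0.11 ± 0.145) or ebs1Δ (0.21 ± 0.195). URA3, deleted in BY4741, had 0 reads in each library, and MET17, also deleted there, had at most 1. HIS3, which BY4741 lacks in part, had 2156 to 6658 reads per library in all 4 genotypes. It was no check of the labels. Of the genes next to the 3 deleted ones, none was called in nmd4Δ or ebs1Δ. In upf1Δ, ISF1 beside NAM7 rose by 1.18 ± 0.215 and STE11 beside NMD4 by 0.63 ± 0.048, GRX8 rose by 0.31, and SEC14, UME6 and MSS4 fell by 0.17, 0.16 and 0.26.

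**Figure D1:**
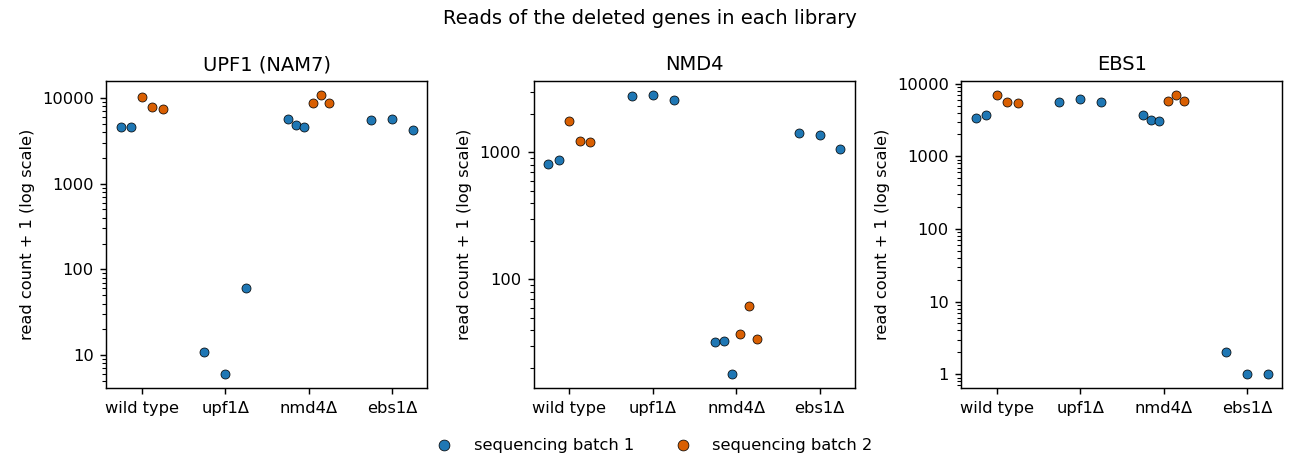
Read counts plus 1 of UPF1 (NAM7), NMD4 and EBS1, on log axes, with 1 point per library and colour for the sequencing batch. Each gene is near 0 in its own deletion, with 5 to 59 reads of NAM7 in upf1Δ, 17 to 61 of NMD4 in nmd4Δ and at most 1 of EBS1 in ebs1Δ.

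Without Upf1, most of 19 mRNAs documented as NMD substrates, early meiotic genes and genes for the use of poor nitrogen sources and thiamine were more abundant, while most mRNAs of ribosomal proteins and respiratory chain subunits were slightly less abundant. As lists, only the thiamine genes among these passed camera with an estimated correlation (adjusted p = 0.00265), with 0.0645 for NMD substrates, 0.0858 for early meiotic and for nitrogen genes, and 0.253 for ribosomal protein and for respiratory genes. Across all tested genes the change in upf1Δ fell with mean expression (Spearman correlation -0.54). The lists were not compared with other genes of the same expression, so this trend may account for part of their shifts. DAL7, which encodes a malate synthase of allantoin degradation, went from 26.4 ± 0.957 CPM in wild type to 294 ± 10.1 CPM in upf1Δ (SD, n = 3 in each). STN1, which encodes a telomere-capping protein, went from 23.3 ± 0.679 to 137 ± 6.70 CPM. URA1, the dihydroorotate dehydrogenase of pyrimidine synthesis, went the other way, from 1273 ± 42.0 to 208 ± 38.6 CPM. Its log2 change was -2.59 in upf1Δ, -3.025 in nmd4Δ and -2.68 in ebs1Δ. These strains share the KlURA3 marker, so the fall of URA1 cannot be assigned to the loss of Upf1. In all, 2242 genes were higher and 2162 lower, of which 946 rose and 39 fell by 2-fold or more.

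Among called genes with a standard name and a mean of at least 10 CPM, the largest rises included DAL7 (YIR031C, chromosome IX, 413015 to 414679) at 3.47 ± 0.063 and GTO3, an omega-class glutathione transferase gene (YMR251W, chromosome XIII, 772915 to 774015), at 3.34 ± 0.366. IRC10 (YOL015W, chromosome XV, 297078 to 298838) rose by 3.34 ± 0.066 and ULI1 (YFR026C, chromosome VI, 205748 to 206257) by 3.15 ± 0.089. GIT1, which encodes a glycerophosphoinositol permease (YCR098C, chromosome III, 297049 to 298605), rose by 3.09 ± 0.089 and PET18 (YCR020C, chromosome III, 154012 to 154659) by 3.00 ± 0.076. COS12 (3.74 ± 0.339) and the maltose permease genes MAL31 (3.08 ± 0.108) and MAL11 (3.04 ± 0.102) also rose. These belong to gene families, and reads shared among relatives were not examined, so their counts are uncertain. ZPS1, a gene induced by zinc shortage (YOL154W, chromosome XV, 34658 to 35407), had the largest estimate among genes of at least 10 CPM, 4.95 ± 1.12, but its level was 952, 36.2 and 834 CPM in the 3 upf1Δ libraries, and with batch 1 libraries alone its edgeR adjusted p was 0.0557.

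Among the same genes the largest fall was in PHO84, the high-affinity phosphate transporter gene (YML123C, chromosome XIII, 24037 to 25800), at -5.95 ± 1.12, from 291 ± 71.1 to 4.67 ± 4.03 CPM. A gene on the other strand overlaps PHO84, and since the strand setting of the counting is not given in the sources used here, reads of the 2 genes cannot be told apart. URA1 (YKL216W, chromosome XI, 25215 to 26159) fell by 2.59 ± 0.0996 and URA4, which encodes dihydroorotase (YLR420W, chromosome XII, 963785 to 964879), by 1.81 ± 0.057. RIB4, of riboflavin synthesis (YOL143C, chromosome XV, 54595 to 55104), fell by 2.04 ± 0.063 and MDH2, the cytosolic malate dehydrogenase gene (YOL126C, chromosome XV, 81787 to 82920), by 2.03 ± 0.127. Further falls were seen for the polyamine transporter gene TPO2 (-2.51 ± 0.272), the stress gene HSP12 (-2.51 ± 0.193), YRO2 (-2.23 ± 0.210), the cell wall mannoprotein gene CWP1 (-2.16 ± 0.237) and RPI1 (-1.92 ± 0.109).

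Of 19 measured mRNAs documented as NMD substrates in earlier yeast work, 16 rose and 1 fell in upf1Δ, with the same counts adjusted over the list alone (limma camera adjusted p = 2.83e-05, and adjusted p = 0.0645 with an estimated correlation). They included STN1 (2.52 ± 0.052), the telomere-capping gene TEN1 (2.36 ± 0.099), the telomerase genes EST2 (2.19 ± 0.079) and EST3 (1.45 ± 0.053), and CPA1, of arginine synthesis (1.60 ± 0.108). UBP7 fell by 0.31, and CTR2 (0.07) and MAC1 (0.05) did not pass. Of 12 intron-containing meiotic genes 9 rose (9 adjusted over the list alone), among them REC107 (2.38 ± 0.080) and HFM1 (1.88 ± 0.055). Camera gave this list an adjusted p of 0.001, and adjusted p = 0.0412 with an estimated correlation. All 9 early meiotic genes rose (9 adjusted over the list alone; camera adjusted p = 7.64e-04, and adjusted p = 0.0858 with an estimated correlation), including IME2, the meiotic protein kinase gene (2.92 ± 0.080), and ZIP1, of the synaptonemal complex (2.32 ± 0.079). Among 15 mRNAs with upstream reading frames 7 rose and 2 fell, the same adjusted over the list alone, and of 3 mRNAs read through a +1 frameshift 2 rose (EST3 and OAZ1, 2 adjusted over the list alone). Neither list passed camera (adjusted p = 0.525 and 0.336). FLO8 (0.65 ± 0.071) and AQY2 (1.21 ± 0.126), whose reading frames are interrupted in this strain background, both rose, and were the only measured members of their list.

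Among 23 genes of allantoin use and nitrogen catabolite repression, 18 rose and 0 fell in upf1Δ (18 adjusted over the list alone; edgeR made the calls, 18 members had an unadjusted p under 0.05 and limma voom with the matched block called 17 higher). The camera adjusted p was 1.69e-05, and adjusted p = 0.0858 with an estimated correlation. DAL5, an allantoate permease gene, rose by 2.86 ± 0.072, the urea transporter gene DUR3 by 1.93 ± 0.060 and GDH2, of glutamate breakdown, by 1.70 ± 0.046. Of 22 thiamine genes 19 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 1.88e-06, and adjusted p = 0.00265 with an estimated correlation), with THI21 at 2.55 ± 0.067, THI22 at 2.32 ± 0.055 and THI6 at 1.38 ± 0.048. Several THI genes are near-identical copies. Of 20 seripauperin and TIR cell wall genes 18 rose (18 adjusted over the list alone; camera adjusted p = 9.58e-07, and adjusted p = 0.0234 with an estimated correlation), with TIR4 at 2.93 ± 0.092, and reads of the PAU members are likewise shared among copies.

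Ribosomal protein genes fell in 123 of 132 cases and rose in 4 (the same adjusted over the list alone), with a median change of -0.33. RPS6A fell by 0.48 ± 0.054, whereas RPL22B, whose unspliced transcript is a known NMD target, rose by 1.40 ± 0.062. Camera gave an adjusted p of 1.06e-16, and adjusted p = 0.253 with an estimated correlation. Ribosome assembly genes fell in 32 of 35 cases (33 adjusted over the list alone), with NOP56 at -0.50 ± 0.071 (camera adjusted p = 1.08e-05, and adjusted p = 0.582 with an estimated correlation). Of 33 respiratory chain and ATP synthase genes 31 fell (32 adjusted over the list alone), COX4 by 0.77 ± 0.071 (camera adjusted p = 3.70e-08, and adjusted p = 0.253 with an estimated correlation). Of 17 glycolysis genes 12 fell (12 adjusted over the list alone), PGI1 by 0.45 ± 0.072 (camera adjusted p = 0.00835, and adjusted p = 0.582 with an estimated correlation). All 7 genes of MATa cells fell (7 adjusted over the list alone), the pheromone gene MFA1 by 1.39 ± 0.132 and the protease gene BAR1 by 1.24 ± 0.103 (camera adjusted p = 0.00102, and adjusted p = 0.253 with an estimated correlation). Of 4 genes of MATalpha cells, the other haploid type, SAG1 (2.30 ± 0.054) and STE3 (1.02 ± 0.088) rose, 2 also adjusted over the list alone, while MF(ALPHA)1 (0.71) and MF(ALPHA)2 (-0.77) did not pass (camera adjusted p = 0.162).

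Among 23 mRNA decay and translation termination genes 4 rose and 15 fell, or 4 and 16 adjusted over the list alone, including SUP35, the release factor gene, at -0.61 ± 0.062 (camera adjusted p = 0.011, and adjusted p = 0.0901 with an estimated correlation). Without the 3 deleted genes, 2 of 20 rose and 14 fell (camera adjusted p = 0.00228, and adjusted p = 0.0735 with an estimated correlation). Of 12 pyrimidine genes 8 fell and 2 rose (the same adjusted over the list alone), with URA10 (2.34 ± 0.071) and URA6 (0.90 ± 0.051) opposite to URA1 and URA4 (camera adjusted p = 0.0623). The remaining lists did not pass camera as groups in upf1Δ and held members that went both ways. They were Gcn4-dependent amino acid synthesis (5 rose and 9 fell of 27, 5 and 8 adjusted over the list alone; adjusted p = 0.286), stress response (10 and 7 of 28, the same adjusted over the list alone; 0.709), phosphate (3 and 10 of 18, the same adjusted over the list alone; 0.286) and iron uptake (7 and 2 of 22, 7 and 0 adjusted over the list alone; 0.363). The others were sulfur (5 and 9 of 22, the same adjusted over the list alone; 0.388), glucose-repressed genes (11 and 6 of 23, 11 and 7 adjusted over the list alone; 0.286) and ergosterol synthesis (4 and 11 of 25, 3 and 10 adjusted over the list alone; 0.22). Within these, SSA3, a heat shock chaperone gene, rose by 1.77 ± 0.065, MET1, of sulfate assimilation, by 2.44 ± 0.067, FRE3, a ferric reductase gene, by 2.24 ± 0.188 and SER3, of serine synthesis, by 1.36 ± 0.078. An intergenic transcript runs into SER3, so its count is uncertain.

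The 390 tested identifiers of the table that the RefSeq annotation does not list were higher in 210 cases and lower in 20 (208 and 17 adjusted over the list alone; camera adjusted p = 1.83e-05, and adjusted p = 0.05003 with an estimated correlation). Of 266 genes with an intron 80 rose and 125 fell (80 and 126 adjusted over the list alone; camera adjusted p = 0.0637), and without ribosomal protein genes 76 of 177 rose and 43 fell (the same adjusted over the list alone; 0.0865). The rises included IWR1 at 1.91 ± 0.057 and NBL1 at 2.73 ± 0.093. All 3 measured pseudogenes rose, AAD6, FLO8 and CRS5 (3 adjusted over the list alone; camera adjusted p = 0.0492, and adjusted p = 0.13 with an estimated correlation), and AAD6 has near-identical relatives. The blocked fit called 2186 genes higher and 2086 lower in upf1Δ, and batch 1 libraries alone gave 2101 and 1878. The 3 mitochondrially encoded genes tested were not called in any deletion by edgeR (camera adjusted p = 0.622 in upf1Δ, 0.733 in nmd4Δ and 0.714 in ebs1Δ).

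**Figure D2:**
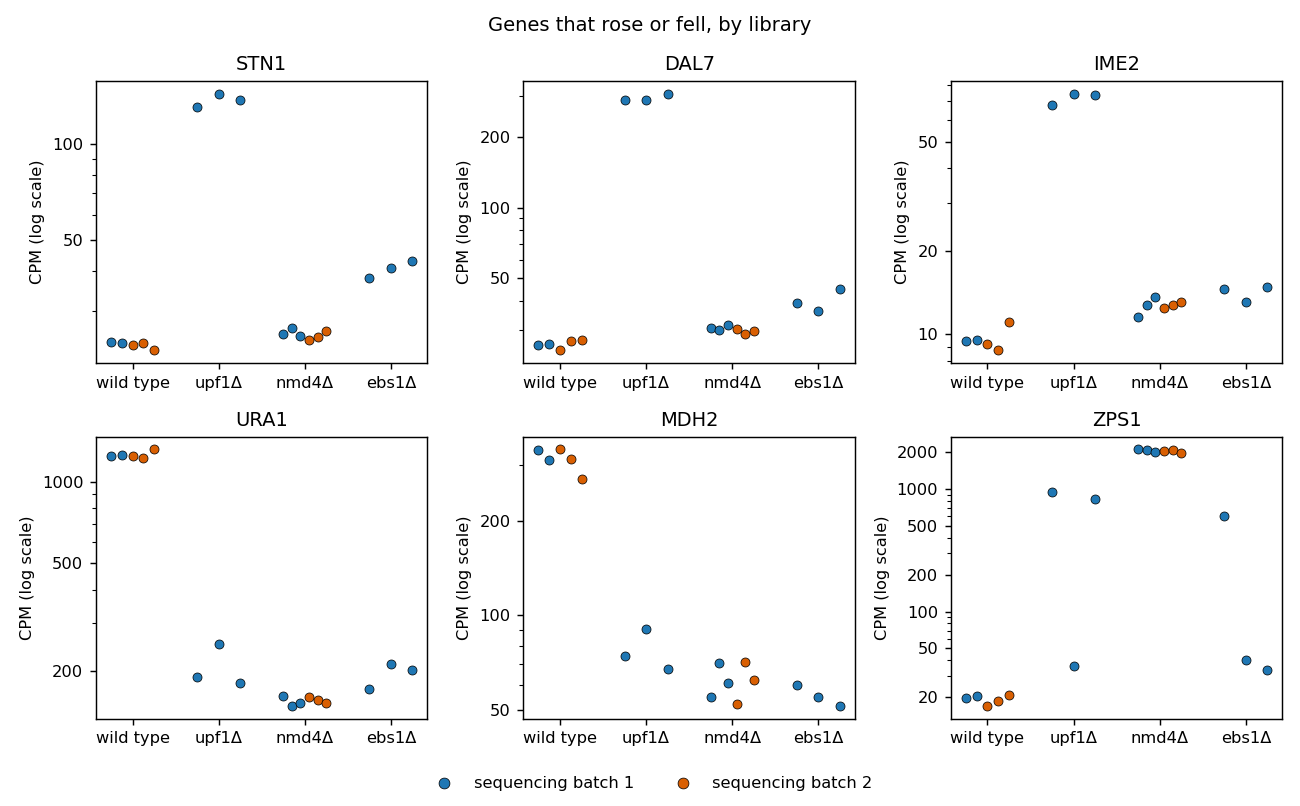
CPM on log axes of 6 genes, with 1 point per library, grouped by genotype and coloured by sequencing batch. STN1, DAL7 and IME2 are highest in upf1Δ, URA1 lies between 149 and 252 CPM in the deletion libraries against 1230 to 1322 in wild type, and ZPS1 is at 1959 CPM or more in nmd4Δ but varies from 36.2 to 952 CPM within upf1Δ.

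Without Nmd4 fewer genes were called than without Upf1. The largest rises were in 2 zinc-responsive genes, which were also high in 2 of the 3 upf1Δ libraries and in 1 of the 3 ebs1Δ libraries. ZPS1 went from 19.5 ± 1.16 CPM in wild type to 2052 ± 59.96 CPM in nmd4Δ (SD, n = 3 in each), and ZRT1, the high-affinity zinc transporter gene, from 204 ± 31.9 to 3153 ± 235 CPM. URA1 fell from 1273 ± 42.0 to 155 ± 4.89 CPM and RIB4 from 552 ± 36.5 to 123 ± 1.19 CPM. Both also fell in upf1Δ and ebs1Δ, which share the KlURA3 marker with nmd4Δ. In nmd4Δ 836 genes were called higher and 889 lower, 36 and 23 of them by 2-fold or more, and most called changes were small, with a median size of 0.22. The blocked fit called 16 rises and 17 falls of 2-fold or more, batch 1 libraries alone 15 and 16, and 1 library per matched set, with no batch term, 23 and 14.

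Among genes with a standard name and a mean of at least 10 CPM, the rises were led by ZPS1 (6.74 ± 1.02), ZRT1 (YGL255W, chromosome VII, 20978 to 22108; 3.92 ± 0.719), VEL1 (YGL258W, chromosome VII, 11110 to 11730; 3.50 ± 0.278) and the alcohol dehydrogenase gene ADH4 (YGL256W, chromosome VII, 15159 to 16307; 2.46 ± 0.157). The peptide transporter gene PTR2 (YKR093W, chromosome XI, 615730 to 617535) rose by 2.05 ± 0.072, the vacuolar zinc transporter gene ZRT3 by 1.39 ± 0.198, ZAP1, the zinc-responsive transcription factor gene, by 1.30 ± 0.194 and the flavohaemoglobin gene YHB1 by 0.96 ± 0.071. COS12 (1.53 ± 0.271) has near-identical relatives, and RTC4 (1.24 ± 0.249) lost its call in the blocked fit (limma adjusted p = 0.0536). Falls were led by URA1 (-3.02 ± 0.073), MDH2 (-2.34 ± 0.092), RIB4 (-2.18 ± 0.046), URA4 (-1.69 ± 0.041) and TPO2 (-1.55 ± 0.178). The exporter gene AQR1 (-1.44 ± 0.283), the uridine permease gene FUI1 (-1.35 ± 0.146), HSP12 (-1.31 ± 0.133) and ADR1, an activator of glucose-repressed genes (-1.11 ± 0.077), followed. TOD6 (-0.64 ± 0.175) was not called in the blocked fit (limma adjusted p = 0.143).

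Documented NMD substrates as a list did not pass in nmd4Δ, with 6 of 19 higher and 3 lower, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.0807). This rests on single libraries, since the camera adjusted p was 0.0385 without wild type replicate 2, 0.0453 without wild type replicate 4 and 0.02507 without nmd4Δ replicate 5. EST3 rose by 0.54 ± 0.040, COX19 by 0.33 ± 0.089 and CPA1 by 0.27 ± 0.081, while STN1 (0.10), TEN1 (0.18) and EST2 (-0.02) did not pass. Thiamine genes rose in 12 of 22 cases and fell in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 5.11e-04, and adjusted p = 0.0229 with an estimated correlation), including PET18 (0.48 ± 0.060) and THI6 (0.28 ± 0.036). Seripauperin and TIR genes rose in 13 of 20 cases (18 adjusted over the list alone; camera adjusted p = 1.16e-06, and adjusted p = 0.0229 with an estimated correlation), TIR4 by 0.46 ± 0.073. In the blocked fit 4 thiamine genes and 3 seripauperin and TIR genes were called higher. The camera values above take matched libraries as separate. With 1 library per matched set and no batch term, the camera adjusted p was 5.94e-04 for thiamine genes and 6.75e-09 for seripauperin and TIR genes. Ribosome assembly genes fell in 32 of 35 cases (33 adjusted over the list alone), NOP2 by 0.39 ± 0.072 and DBP3 by 0.41 ± 0.080 (camera adjusted p = 3.76e-13, and adjusted p = 0.375 with an estimated correlation), and the blocked fit called 16 of them lower.

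Pyrimidine genes fell in 7 of 12 cases and rose in 1 (the same adjusted over the list alone; camera adjusted p = 1.18e-04, and adjusted p = 0.196 with an estimated correlation). Among them, URA1 and URA4 fell in each deletion, and the deletions share the KlURA3 marker. Sulfur genes fell in 8 of 22 cases and rose in 1 (the same adjusted over the list alone; camera adjusted p = 0.00592, and adjusted p = 0.0936 with an estimated correlation), led by STR3 (-0.69 ± 0.086) and MET6 (-0.34 ± 0.050). Genes of MATa cells fell in 5 of 7 cases (5 adjusted over the list alone; 0.00568, and adjusted p = 0.386 with an estimated correlation), led by BAR1 (-0.52 ± 0.074). Glycolysis genes rose in 6 of 17 cases and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0104, and adjusted p = 0.573 with an estimated correlation), with the enolase genes ENO1 (0.51 ± 0.094) and ENO2 (0.25 ± 0.050) up and ADH1 (-0.37 ± 0.071) down. Ribosomal protein genes fell in 13 of 132 cases (4 adjusted over the list alone; 0.00113, and adjusted p = 0.708 with an estimated correlation). Allantoin and nitrogen genes rose in 7 of 23 cases and fell in 1 (the same adjusted over the list alone; 0.0115, and adjusted p = 0.375 with an estimated correlation), but the blocked fit called none of them higher. By that limma fit 0 were higher and 1 lower, GLN1 (-0.23 ± 0.041 in edgeR), against 8 at an unadjusted p under 0.05 there. Phosphate genes fell in 3 of 18 cases and rose in 1 (the same adjusted over the list alone; 0.0115, and adjusted p = 0.581 with an estimated correlation), and decay factors fell in 8 of 23 cases and rose in 1 (9 and 1 adjusted over the list alone; 0.0115, and adjusted p = 0.141 with an estimated correlation). Without the deleted genes the decay factors did not pass camera (adjusted p = 0.0558).

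The other lists did not pass camera in nmd4Δ. The counts of higher and lower members were 1 and 1 of 3 frameshift mRNAs (adjusted p = 0.496), 3 and 3 of 15 mRNAs with upstream reading frames (0.964), 2 and 2 of 27 Gcn4-dependent genes (0.922) and 2 and 0 of 12 intron-containing meiotic genes (0.196), all unchanged when adjusted over the list alone. They were 4 and 4 of 28 stress genes (4 and 5 adjusted over the list alone; 0.291), 3 and 1 of 22 iron genes (the same adjusted over the list alone; 0.278), 2 and 3 of 33 respiratory genes (2 and 2 adjusted over the list alone; 0.922) and 4 and 10 of 23 glucose-repressed genes (5 and 10 adjusted over the list alone; 0.0558). For ergosterol genes they were 2 and 1 of 25 (0.214), for MATalpha genes 2 and 0 of 4 (0.165) and for early meiotic genes 2 and 0 of 9 (0.0838), the same adjusted over the list alone. IME2 rose by 0.41 ± 0.063. AQY2 rose by 0.48 ± 0.096, and FLO8 (-0.12) did not pass. Identifiers absent from RefSeq were higher in 57 of 390 cases and lower in 7 (41 and 4 adjusted over the list alone; camera adjusted p = 0.0129, and adjusted p = 0.317 with an estimated correlation). Genes with an intron were higher in 31 of 266 cases and lower in 26 (25 and 19 adjusted over the list alone; 0.868), without ribosomal protein genes in 31 and 15 of 177 (30 and 12 adjusted over the list alone; 0.171), and among 3 pseudogenes AAD6 alone was called (0.22 ± 0.050, 1 adjusted over the list alone; 0.868) and lost its call in the blocked fit (limma adjusted p = 0.0805).

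With matched libraries as a block the counts for nmd4Δ were 250 higher and 266 lower, against 836 and 889, and 512 of the 516 genes were also called in the fit above. Batch 1 libraries alone gave 89 and 43 and batch 2 libraries alone 418 and 449, and without wild type replicate 2 or 4 the lower calls numbered 441 or 532. With batch 1 libraries alone ZPS1 was not called (edgeR adjusted p = 0.158), and neither were ZRT1, ZRT3, ZAP1, COS12 and AQR1. Even so, batch 1 levels of ZPS1 were 2008.6 to 2114.5 CPM in nmd4Δ against 19.7 and 20.3 in wild type. For ZRT1 they were 3005 to 3438 against 182 and 250. That fit estimates the spread over all genotypes, and ZPS1 ran from 36.2 to 952 CPM in upf1Δ and from 33.2 to 609 in ebs1Δ. DESeq2's median-of-ratios scaling in edgeR moved the split to 983 higher and 723 lower. Of 108 genes that the naming rule gave for nmd4Δ and that edgeR called, 35 were not called in the blocked fit. They included PAU24 (limma adjusted p = 0.0789), PAU4 (0.2435), the proline permease gene PUT4 (0.1269), DAL3 (0.0919), DAL1 (0.0858), FIT1 (0.1552), HFM1 (0.175), AMA1 (0.4626), STE3 (0.0512), SAG1 (0.1315), PGA1 (0.214), MAC1 (0.158), DCP1 (0.131) and HRR25 (0.0989). By list, the blocked fit called 3 NMD substrates, 2 early meiotic genes, 1 frameshift mRNA and 1 respiratory gene higher, and 5 pyrimidine genes, 5 sulfur genes, 3 stress genes, 2 genes of MATa cells, 2 decay factors (SUP35 and the deleted gene NMD4 itself), 2 Gcn4-dependent genes and 1 ribosomal protein gene lower. It called 3 glycolysis genes higher and 1 lower, 1 glucose-repressed gene higher and 5 lower, 1 phosphate gene higher and 2 lower, and 1 of each direction among iron genes, ergosterol genes and mRNAs with upstream reading frames. Of identifiers absent from RefSeq it called 8 higher and 4 lower, and of genes with an intron 7 and 3. Among intron-containing meiotic genes and genes of MATalpha cells limma called 0, with 1 and 2 at an unadjusted p under 0.05, where edgeR called 2 in each. The effect of the deletion was also compared between batches, with a genotype by batch interaction over 6058 genes. edgeR called 0 genes, with 69 at an unadjusted p under 0.05, and DESeq2 also called 0, with 41. Since the batch 2 libraries match those of batch 1, this is not a test on separate cultures.

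Without Ebs1, 12 of 19 documented NMD substrates and 11 of 22 thiamine genes rose, and URA1, RIB4 and MDH2 fell to levels near those of the other deletions. With an estimated correlation the thiamine list passed camera (adjusted p = 0.00263) and the NMD list did not (adjusted p = 0.0518). STN1 went from 23.3 ± 0.679 CPM in wild type to 40.6 ± 2.49 CPM in ebs1Δ and EST3, a telomerase subunit gene whose mRNA is read through a frameshift, from 29.0 ± 0.569 to 48.5 ± 0.392 CPM (SD, n = 3 in each). MDH2 went from 307 ± 32.3 to 55.7 ± 4.33 CPM. In total 863 genes were higher and 455 lower, 54 and 16 of them by 2-fold or more. The rises of 2-fold or more numbered 30 in the blocked fit, 95 without the batch term and 129 with matched libraries summed and no batch term.

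Among genes with a standard name and a mean of at least 10 CPM, large rises were seen in PTR2 (1.76 ± 0.095), YHB1 (1.17 ± 0.093), GIT1 (0.96 ± 0.096), PPT2, of mitochondrial acyl carrier protein modification (YPL148C, chromosome XVI, 272294 to 272815; 0.96 ± 0.085), the kinase gene KDX1 (0.90 ± 0.068), the arginine permease gene ALP1 (0.88 ± 0.141) and the spore wall gene DIT1 (0.87 ± 0.106). COS12 (2.36 ± 0.353) and AAD4 (0.89 ± 0.084) also rose but belong to families of near-identical copies. ZPS1 had an estimate of 3.54 ± 1.09 that came from 1 library, with 609, 40.4 and 33.2 CPM in the 3 libraries. Without ebs1Δ replicate 1 it was 0.91, and the blocked fit did not call it (limma adjusted p = 0.306). Falls were led by URA1 (-2.68 ± 0.10), MDH2 (-2.51 ± 0.130), RIB4 (-2.21 ± 0.064), TPO2 (-1.79 ± 0.258), URA4 (-1.67 ± 0.057), HSP12 (-1.62 ± 0.185) and ADR1 (-1.16 ± 0.108). TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene, fell by 1.00 ± 0.180, DOT6 by 0.94 ± 0.163 and YRO2 by 0.87 ± 0.198.

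Of the 19 documented NMD substrates 12 rose and 0 fell in ebs1Δ (12 and 0 adjusted over the list alone; edgeR, with 12 at an unadjusted p under 0.05, and 10 and 0 in the blocked limma fit). The camera adjusted p was 1.74e-06, and adjusted p = 0.0518 with an estimated correlation. TEN1 rose by 0.81 ± 0.105, STN1 by 0.77 ± 0.054, EST3 by 0.73 ± 0.054 and CPA1 by 0.72 ± 0.108. Thiamine genes rose in 11 of 22 cases (15 adjusted over the list alone; camera adjusted p = 1.82e-06, and adjusted p = 0.00263 with an estimated correlation), THI6 by 0.67 ± 0.049 and PET18 by 0.60 ± 0.084. Early meiotic genes rose in 5 of 9 cases (5 adjusted over the list alone; camera adjusted p = 7.25e-04, and adjusted p = 0.0969 with an estimated correlation), IME2 by 0.57 ± 0.088, and intron-containing meiotic genes in 4 of 12 (4 adjusted over the list alone; camera adjusted p = 0.00437, and adjusted p = 0.0672 with an estimated correlation), HFM1 by 0.58 ± 0.058. Allantoin and nitrogen genes rose in 7 of 23 cases (10 adjusted over the list alone; camera adjusted p = 0.00347, and adjusted p = 0.225 with an estimated correlation), DAL7 by 0.60 ± 0.064. Seripauperin and TIR genes rose in 8 of 20 cases (13 adjusted over the list alone; camera adjusted p = 5.05e-05, and adjusted p = 0.0534 with an estimated correlation), TIR4 by 0.62 ± 0.10, and the blocked fit called 3.

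Respiratory chain and ATP synthase genes fell in 18 of 33 cases in ebs1Δ (23 adjusted over the list alone), QCR7 by 0.42 ± 0.075 (camera adjusted p = 1.06e-08, and adjusted p = 0.234 with an estimated correlation). Ribosomal protein genes fell in 26 of 132 cases and rose in 1, RPL22B (0.34 ± 0.063), or 24 and 1 adjusted over the list alone (camera adjusted p = 1.94e-09, and adjusted p = 0.381 with an estimated correlation). Stress genes fell in 6 of 28 cases and rose in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 4.72e-04, and adjusted p = 0.483 with an estimated correlation), and glycolysis genes fell in 4 of 17 (4 adjusted over the list alone; 3.35e-04, and adjusted p = 0.381 with an estimated correlation). Pyrimidine genes fell in 4 of 12 cases (4 adjusted over the list alone; 8.24e-04, and adjusted p = 0.225 with an estimated correlation). URA1 and URA4, which fell in each deletion, were among them. Of 18 phosphate genes 2 fell and 1 rose (3 and 1 adjusted over the list alone; 0.027, and adjusted p = 0.6 with an estimated correlation), and of 7 genes of MATa cells 3 fell (4 adjusted over the list alone; 0.0147, and adjusted p = 0.381 with an estimated correlation). SAG1 (0.46 ± 0.056) and STE3 (0.27 ± 0.091) of the 4 genes of MATalpha cells rose (2 adjusted over the list alone; 0.0297, and adjusted p = 0.13 with an estimated correlation), the second without a call in the blocked fit (limma adjusted p = 0.105). Of 3 frameshift mRNAs 2 rose (2 adjusted over the list alone; 0.043, and adjusted p = 0.234 with an estimated correlation). Of 23 decay factors 5 fell and NMD4 rose (5 and 1 adjusted over the list alone; 0.0379, and adjusted p = 0.22 with an estimated correlation). EBS1 itself is 1 of the 5, and without the deleted genes 4 of 20 fell (camera adjusted p = 0.0265, and adjusted p = 0.214 with an estimated correlation). With 1 library per matched set and no batch term, neither the frameshift mRNAs (camera adjusted p = 0.0598) nor the 23 decay factors (0.08315) passed.

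No group call was made in ebs1Δ for mRNAs with upstream reading frames, of which 3 of 15 rose (3 adjusted over the list alone; camera adjusted p = 0.45), or for Gcn4-dependent genes, of which 2 of 27 rose and 2 fell (0 and 0 adjusted over the list alone; 0.714). The ribosome assembly list did not pass either (0.183). Of its 35 genes edgeR called 0, 0 had an unadjusted p under 0.05, and 0 were called in the blocked limma fit. Iron (2 rose and 0 fell of 22, 1 and 0 adjusted over the list alone; 0.157), sulfur (3 and 4 of 22, the same adjusted over the list alone; 0.714), glucose-repressed (3 and 4 of 23, 3 and 5 adjusted over the list alone; 0.714) and ergosterol genes (1 and 1 of 25, the same adjusted over the list alone; 0.12) did not pass. AQY2 (0.32) and FLO8 (0.12) were not called. Identifiers absent from RefSeq were higher in 59 of 390 cases and lower in 2 (50 and 0 adjusted over the list alone; 0.0026, and adjusted p = 0.202 with an estimated correlation). Genes with an intron were higher in 20 of 266 cases and lower in 38 (23 and 39 adjusted over the list alone; 0.003, and adjusted p = 0.311 with an estimated correlation), without ribosomal protein genes in 19 and 18 of 177 (the same adjusted over the list alone; 0.31), and AAD6 rose (0.53 ± 0.068; 1 of 3 pseudogenes adjusted over the list alone, 0.14).

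The blocked fit called 648 genes higher and 359 lower in ebs1Δ, and batch 1 libraries alone 541 and 158. It called 31 identifiers absent from RefSeq higher, 14 genes with an intron higher and 31 lower, 13 respiratory genes lower and 2 decay factors lower. These 2 were the deleted gene EBS1 and SCD6. Fewer lower calls were made without wild type replicate 1 (258) or without ebs1Δ replicate 2 (264) or 3 (301).

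Genes raised without Upf1 were shifted the same way, by smaller amounts, in the other deletions. The 946 genes raised 2-fold or more in upf1Δ had a median log2 change of 1.70 there, 0.24 in nmd4Δ and 0.45 in ebs1Δ. Of these genes edgeR, with matched libraries as separate, called 389 higher and 9 lower in nmd4Δ, and 517 higher in ebs1Δ. The blocked fit called only 250 genes of any kind higher in nmd4Δ. Since the list was chosen on these samples, it is not independent evidence of its direction or size in upf1Δ.

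The planned test for nmd4Δ took the list from batch 1 and the effect from batch 2. Of 1978 measured genes 333 were higher and 19 lower, and 76.3% had a positive change, against 36.9% of other genes (camera p = 3.06e-23, and p = 4.41e-04 with an estimated correlation). No library was used on both sides, but wild type replicates 3 and 4 match replicates 1 and 2, so the controls were not independent. In ebs1Δ, 832 of the 2242 genes raised in upf1Δ were higher and 20 lower, and 85.7% had a positive change (camera p = 2.75e-62, and p = 2.69e-07 with an estimated correlation). Between upf1Δ and nmd4Δ, 672 genes were higher in both and 620 lower in both. Independent lists of those sizes would share 304 and 312, and 88 genes were called in opposite directions. The overlap counts here and below use edgeR calls that take matched libraries as separate. In nmd4Δ the blocked fit called only 250 genes higher and 266 lower in all, and overlaps were not counted with it. Between upf1Δ and ebs1Δ the numbers were 832 and 386, against 314 and 160 for independent lists, with 21 opposite. Between nmd4Δ and ebs1Δ they were 413 and 155, against 117 and 65.6, with 17 opposite.

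Because the comparisons share wild type libraries, part of the correlation between their changes arises with no effect at all. The Pearson correlation of log2 changes across genes, which are not independent replicates, was 0.57 for upf1Δ with nmd4Δ and 0.68 for upf1Δ with ebs1Δ. Simulated unchanged groups set against the same controls gave 0.47 and 0.50. The covariances were 0.141 and 0.212, against 0.0107 and 0.0144 in the simulation. For nmd4Δ with ebs1Δ the correlation was 0.55 against 0.45, and the covariance 0.0596 against 0.0106, but the share of genes with the same sign was 64.4%, below the 66.4% of the simulation, and the Spearman correlation was 0.42. The same-sign shares with upf1Δ were 71.1% for nmd4Δ against 66.8% and 78.0% for ebs1Δ against 67.8%. With wild type libraries divided between the comparisons by matched set, which was done after the libraries had been compared, the correlations with upf1Δ were 0.50 and 0.49 for nmd4Δ and 0.65 and 0.58 for ebs1Δ. Genes higher in both then numbered 637 and 285 for nmd4Δ, where independent lists would share 354 and 116. For ebs1Δ they numbered 734 and 733, against 269 and 285.

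**Figure D3:**
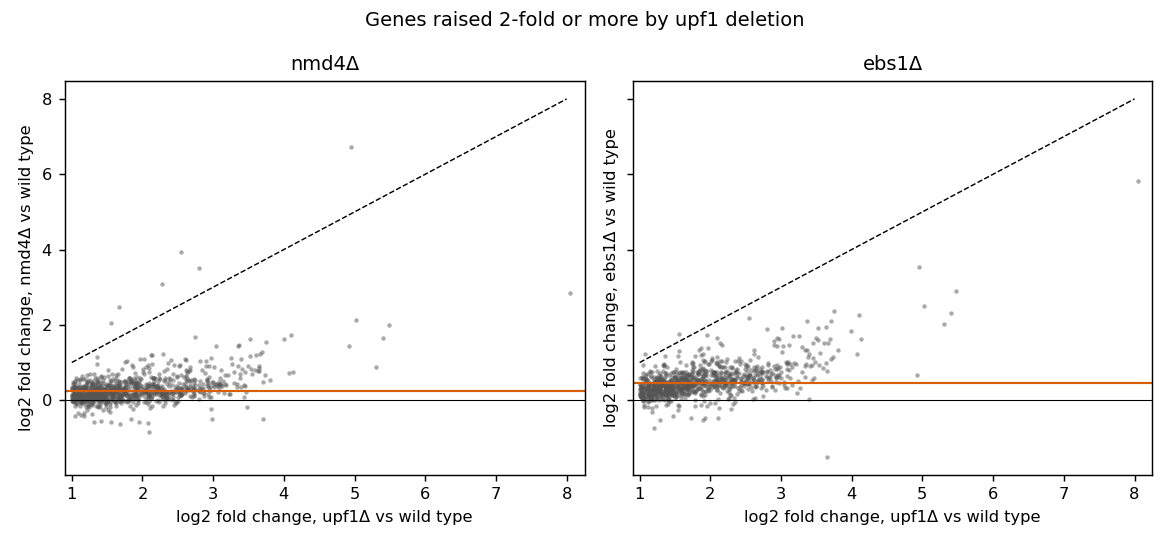
Log2 fold changes in nmd4Δ and ebs1Δ (vertical axes) against those in upf1Δ (horizontal axes) for genes raised 2-fold or more in upf1Δ, without NMD4, 1 point per gene. The dashed line marks equal change and the orange line the median over all 946 genes, 0.24 in nmd4Δ and 0.45 in ebs1Δ.

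Compared directly with upf1Δ, nmd4Δ had 1907 genes higher and 2218 lower, 19 and 817 of them by 2-fold or more. Without nmd4Δ replicate 2 the 19 became 11. DAL7 was lower in nmd4Δ than in upf1Δ (-3.27 ± 0.058), as were IRC10 (-2.99 ± 0.060), ULI1 (-2.95 ± 0.082), GTO3 (-2.91 ± 0.333) and MAL31 (-2.77 ± 0.099). PHO84 (4.90 ± 1.06), CWP1 (2.28 ± 0.229), RPI1 (1.83 ± 0.105), YRO2 (1.61 ± 0.199) and the cell wall stress sensor gene WSC4 (1.48 ± 0.168) were higher in nmd4Δ. Against upf1Δ, ebs1Δ had 1690 genes higher and 2084 lower, 13 and 689 by 2-fold or more. Among genes of at least 10 CPM the largest differences were in DAL7 (-2.87 ± 0.064), MAL31 (-2.76 ± 0.111), ULI1 (-2.75 ± 0.089), IRC10 (-2.72 ± 0.065) and MAL11 (-2.65 ± 0.104) on the lower side. PHO84 (4.87 ± 1.08), CWP1 (1.60 ± 0.232), YRO2 (1.35 ± 0.208), RPI1 (1.25 ± 0.112) and NCA3 (1.21 ± 0.240) were higher. The blocked fit called 1792 higher and 2121 lower for nmd4Δ and 1589 and 1970 for ebs1Δ, and batch 1 libraries alone gave 1674 and 2124, and 1519 and 2011.

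Between nmd4Δ and ebs1Δ the largest rises among the named genes were in zinc-responsive ones, which were not tested as a list here. In nmd4Δ VEL1 was higher by 2.75 ± 0.351 and ADH4 by 1.97 ± 0.197, while ZPS1 was higher by 3.20 ± 1.09, with an edgeR adjusted p of 0.0485. TDH1 (1.35 ± 0.173) and GSY1, a glycogen synthase gene (1.02 ± 0.253), were also higher in nmd4Δ. AQR1 (-1.48 ± 0.359), VID24 (-0.86 ± 0.217) and TOD6 (-0.79 ± 0.225) were lower in nmd4Δ, as were PRM7 (-1.81 ± 0.540) and MIG2 (-0.79 ± 0.221), whose calls did not hold in the blocked fit (limma adjusted p = 0.158 and 0.0531). In all 617 genes were higher and 986 lower in nmd4Δ, and the blocked fit gave 448 and 624. Batch 1 libraries alone gave 204 and 412. Without ebs1Δ replicate 2 the counts were 252 and 413, and without ebs1Δ replicate 3 they were 275 and 501. Without nmd4Δ replicate 2 the higher calls numbered 347. ZPS1, AQR1, PRM7, MIG2, TOD6 and GSY1 were not called without ebs1Δ replicate 2.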

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

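The matched libraries, the genes lower in all 3 deletions and the zinc genes were chosen for a closer look after their values were seen, and so were their tests. The CPM of COS12 in wild type replicate 5 was 9.58, far from the other 4 wild type libraries, of which the nearest had 5.52 and the lowest 4.14. Of 79 groups tested for such a gap this was the only one, where chance would give about 3.95 if libraries were independent. Matched libraries are not, and a library with a match is less likely to stand apart. Replicate 5 is the only wild type library without a match, so the comparison with 3.95 decides nothing. COS12 has near-identical relatives near chromosome ends.

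Batch 2 libraries matched single libraries of batch 1. Separate cultures might be expected from the replicate names, but the next best matching had a chi-square per degree of freedom at least 3.071 times the matched one, which argues against it. A library sequenced again with sampling noise alone is argued against too, since the lower matched value, with a shift between batches removed for each gene, was 2.675 rather than about 1. The same cultures or RNA in both batches fits, with residual correlations of at least 0.6777 in the 5 matched pairs. A first bound for that last test, unmatched pairs under 0.2, was missed by wild type replicates 2 and 5 (0.4258) and was rewritten after this was seen, because with 2 batch 1 wild type libraries their residuals mirror each other.

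The 10 genes lower by 2-fold or more in all 3 deletions were ADR1, HSP12, URA1, RIB4, MDH2, TPO2, URA4, YNL194C, YNL034W and YNL018C. Chance values of the wild type libraries that the 3 comparisons share are argued against. Genes chosen in the same way on wild type replicates 1 and 3 (19 genes) or on the other 3 (9 genes) had a median log2 change of -1.1739 or lower in each deletion against the left-out replicates. The KlURA3 marker or the strain history that the deletions share may lower them, in place of the deleted gene, and this stays open, since no library with the marker and without a deletion was analysed here. Of the 10 genes 8 were called between deletions. Such calls were common, at 66.9% of tested genes between nmd4Δ and upf1Δ, 61.2% between ebs1Δ and upf1Δ and 26.0% between nmd4Δ and ebs1Δ. The 8 calls therefore cannot decide for or against a shared cause. Only 2 of the 10 (HSP12 and YNL034W) differed by over 1 on the log2 scale, and YNL034W had at most 0.356 CPM in the deletion libraries. YNL018C had at most 0.743 CPM there. YNL194C reached 1.78 CPM in a deletion library, above its lowest wild type value of 1.32 CPM. The falls of these low-count genes are therefore less certain.

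Of 13 zinc-responsive genes listed after the values were seen, 9 rose and 1 fell in nmd4Δ, 8 rose and 3 fell in upf1Δ, and 1 rose in ebs1Δ. Since the list was drawn from these libraries, no test of it is given. RNA of nmd4Δ cells in the upf1Δ libraries with high ZPS1 could give such values, but NAM7 there reached at most 1.189% of its nmd4Δ level, which argues against it. The state of each culture, zinc in the medium or growth, might act in place of the genotype, and this stays open, since ZPS1 varied 26.33-fold among upf1Δ libraries and 18.35-fold in ebs1Δ, but 1.08-fold in nmd4Δ and 1.22-fold in wild type. ZRT1 and ZAP1 varied with ZPS1, but ADH4 and VEL1 did not follow it. In upf1Δ replicate 2, where ZPS1 was 36.2 CPM, ADH4 was still 205 CPM, against 81.6 in wild type replicate 1. In ebs1Δ ADH4 was 119, 111 and 108 CPM, although ZPS1 was 609 CPM in replicate 1 only.

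Wild type libraries shared by 2 comparisons could produce the overlap with upf1Δ. With separate controls the lower correlation was 0.4911 for nmd4Δ and 0.5825 for ebs1Δ, which argues against this as the whole cause. It does not address the KlURA3 marker that the deletions share.

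Libraries were also regrouped in other splits, a test written beforehand. It took the libraries as separate, but each genotype holds 3 matched sets, and 3 sets against 3 make only 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, reached the real count. The real count and the highest of the other splits were 4404 and 2381 of 56 splits in upf1Δ, 1725 and 963 of 100 in nmd4Δ, and 1318 and 403 of 56 in ebs1Δ. They were 4125 and 2929 of 84 between nmd4Δ and upf1Δ, where the split with 2929 is, within batch 1, the real contrast of upf1Δ with nmd4Δ. The split with 2381 in upf1Δ is likewise the real contrast within batch 1. The split with 963 in nmd4Δ sets all wild type libraries and nmd4Δ replicate 3 against the other nmd4Δ libraries. It is the real contrast apart from 1 library. They were 1603 and 4 of 84 between nmd4Δ and ebs1Δ, and 3774 and 335 of 10 between ebs1Δ and upf1Δ.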

How the results depend on the processing

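No deleted gene and no gene named as a largest rise or fall turned in direction while called, nor did a called list or the NMD substrates. Genes named only as list members or neighbours were not followed for this. With matched libraries summed, 2 genes called in upf1Δ and 1 in nmd4Δ against upf1Δ were called with the opposite sign. In nmd4Δ the larger side of the calls turned from lower to higher with DESeq2's scaling (983 higher and 723 lower), DESeq2 itself, matched libraries summed or 1 per set, batch 1 alone, the 2 groups alone and replicate numbers as a block. It also turned without wild type replicate 2 or 4, any 1 upf1Δ library, nmd4Δ replicate 1 or 4, or ebs1Δ replicate 2 or 3. The counts of all called genes for upf1Δ and for both deletions against upf1Δ stayed within 1.5 times of their values throughout. Rises of 2-fold or more in nmd4Δ against upf1Δ numbered 11 without nmd4Δ replicate 2, against 19. For nmd4Δ, batch 1 alone gave 89 higher and 43 lower and batch 2 alone 418 and 449, with fewer samples. Matched libraries as a block gave 250 and 266, summed 267 and 114, and 1 per set 228 and 121. Wherever libraries were summed or reduced to 1 per set the batch term was dropped too, so the 2 changes cannot be told apart. Leaving out single libraries gave 646 to 997 higher and 441 to 988 lower. For ebs1Δ, batch 1 alone gave 541 and 158, the 2 groups alone 481 and 134, 1 library per set 264 lower, and leaving out single libraries 694 to 894 higher and 258 to 510 lower. For nmd4Δ against ebs1Δ, batch 1 alone gave 204 and 412, the block 624 lower, summing 382 higher, 1 per set 216 and 438, and leaving out single libraries 252 to 820 and 413 to 1172. Fewer samples enter most of these fits. Where a single library or the block moved a count, the cause was not tested. The fits on matched libraries were chosen after seeing the data.

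The NMD substrate list had an adjusted p of 0.0645 in upf1Δ and 0.0518 in ebs1Δ with an estimated correlation, and in nmd4Δ, where it was 0.0807, 0.02507 to 0.151 when single libraries were left out. At an adjusted p under 0.01, fewer genes pass, and upf1Δ and nmd4Δ shared 372 higher and 281 lower, upf1Δ and ebs1Δ 544 and 132, and nmd4Δ and ebs1Δ 220 and 47. Of the other values, 4290 stayed the same, 175 weakened, 3 strengthened and 20 moved. The interaction has no alternative without batch, and the fit without robust was not applied to lists.

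Replicate numbers as a block gave 2226 higher and 2155 lower in upf1Δ, 902 and 891 in nmd4Δ, 772 and 355 in ebs1Δ, 1907 and 2219 for nmd4Δ against upf1Δ, 1717 and 2111 for ebs1Δ against upf1Δ, and 702 and 974 for nmd4Δ against ebs1Δ. Of 15 pairs with the same number the correlations ran from -0.03 to 0.31, and 11 matched best with their own number, which leans towards a link. Only 3 exceeded 0.1, and the numbers were not taken as pairs because not every pair did.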

Other observations

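Genes near chromosome ends were higher in each deletion. Of 192 genes within 20 kb of an end, 163 rose and 11 fell in upf1Δ, 94 and 4 in nmd4Δ, and 80 and 4 in ebs1Δ. The test was written beforehand. The median log2 change was 1.6623 in upf1Δ, against 0.35 (95% range 0.22 to 0.51) in 10000 random lists of genes of the same expression. It was 0.2598 in nmd4Δ, against 0.05 (0.02 to 0.08), and 0.4215 in ebs1Δ, against 0.07 (0.03 to 0.12). Camera with an estimated correlation gave p = 1.29e-05, 3.05e-05 and 2.98e-05. Many of these genes belong to families with near-identical copies, so single genes among them are uncertain.

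In all 3 deletions 18 genes were higher by 2-fold or more, a set chosen after seeing the values. It held PTR2 (1.56 in upf1Δ, 2.05 in nmd4Δ and 1.76 in ebs1Δ), LSO1 (3.52, 1.64 and 1.91), ROF1 (1.78, 1.05 and 1.18), SNO4 (4.10, 1.72 and 2.26) and ICS3 (3.61, 1.21 and 1.51), together with ZPS1, COS12 and several PAU genes. By their systematic names COS12 (YGL263W), YGL262W, PAU11 (YGL261C), YPS5 (YGL259W) and YGL258W-A lie close together. They may not be separate observations. The set rests on edgeR calls that take matched libraries as separate. Members without a call in the blocked fit include PAU24 in nmd4Δ (limma adjusted p = 0.0789) and ZPS1 in ebs1Δ (0.306), whose rise there came from 1 library.

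Across genes the log2 change fell with mean expression, with a Spearman correlation of -0.54 in upf1Δ, -0.26 in nmd4Δ and -0.41 in ebs1Δ. Apart from the genes near chromosome ends, the gene lists were not compared with other genes of the same expression.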
